A study of Mus musculus with 2 samples.

How the data were processed

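The series holds 1 RNA library and 1 hashtag library of cells sorted after 8 days of bone marrow culture from mice aged 15 days, both read from a single feature matrix. Whole-number counts of unique molecular identifiers (UMIs) per gene and barcode were used as the authors deposited them. They were made with Cell Ranger 9.0.1, per the file headers, and the submitters' processing notes name the mouse build GRCm39. The library kit was Chromium Single Cell 3′ version 4, per the labels' protocols. Read filters and the gene annotation are not given in the sources used here. The matrix was not filtered for cells: it held 3099358 barcodes, 548677300 gene UMIs and 42639649 hashtag UMIs, and had 33696 genes and 3 antibody rows. No row for a transgene was among them. Gene symbols and identifiers were taken from the features of the matrix. Every column belonged to the samples.

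A barcode counted as a cell when its gene UMIs reached 10% of the 99th percentile of the 10000 barcodes with most UMIs (4730 here) and it had at least 500 genes and at most 10% mitochondrial UMIs. Of 28313 barcodes above the minimum 16 were removed, which left 28297 cells with 93.9% of all gene UMIs. Each hashtag was called from a 2-part Gaussian mixture of log counts. Cells with 2 or more hashtags (3335, 11.8%) were removed as doublets, and 256 cells had no hashtag. Median UMIs of a cell's own hashtag were 689, 908.5 and 988 for hashtags 10, 11 and 12, against 18 to 20 for the others. Scrublet, run through scanpy 1.11.5 with an expected share of 10%, called 2119 cells (7.49%), among them 40.5% of the cells with 2 or more hashtags and 768 others, which were removed too. From the share of cells with 2 or more hashtags, 1683 doublets within a hashtag were expected, more than were called. The median share of mitochondrial UMIs was 1.78%. Droplets with 50 to 299 UMIs (118837 of them, median 163 gene UMIs) gave the profile of free RNA, about 1.01% of the median cell.

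Cells were normalised to equal totals, log-transformed and clustered with scanpy from 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (igraph 0.11.9). The genes of the fixed lists were left out of the features. Cluster names came from marker lists fixed before the data were examined. A cluster was named for another cell type when at least 3 of that type's markers were among its 30 leading genes. Otherwise the mean log2 level of DC markers (types 1 and 2 included) was set against that of ILC3 markers, each centred over clusters, and a gap of at least 0.75 with at least 3 markers detected in 50% of cells gave the class. A cluster with more markers of another type than of its own among its top 10 genes, or under 20 cells, stayed unnamed. This rule and the gap were set after seeing the data. It left out cluster 13 (545 cells), cluster 18 (86 cells, median 6182 UMIs) and cluster 21 (13 cells). The named classes are rebuilt from markers and need not match the study's own.

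Cells are not replicates and there is 1 library, so no test was made. UMIs were summed over the cells of a class and given as CPM, counts scaled to equal class totals, with exact Poisson intervals, and shares of cells with exact binomial (Clopper-Pearson) intervals, both for counting error only. A list member counted as higher or lower where the ratio was at least 2-fold and had the same direction in every hashtag population with at least 20 cells of both classes. Members with fewer than 50 UMIs over both classes were not compared, and a class with 0 UMIs was set to 3 counts. A list's median log2 ratio was placed among 10000 random lists of the same size matched on expression, as a percentile. The median over all 15876 genes compared was -0.13, and scaling by the median ratio of genes with at least 50 CPM in both classes moved every log2 ratio up by 0.10 (a shift of -0.10 taken off). It left no named gene's call changed, with 75 members higher and 66 lower. For shares of cells with a UMI, cells were thinned to 10500 UMIs, the 10th percentile of both classes rounded down to a multiple of 500.

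The size rule was tested on simulated counts for the DC-like over ILC3-like comparison, with 15837 genes and 200 of them changed. It called 70 of 71 genes changed 6-fold and 61 of 62 changed 3-fold in the true direction, 1 of 67 changed 1.5-fold, and 11 of 15637 unchanged genes. With nothing changed, 0 of 18 lists fell in the outer 5 percent of random lists. Counts were drawn as independent Poisson values from the pooled profile, with the classes given. Clustering, naming, variation among cells and shared regulation of list members were not simulated. The percentiles are therefore not calibrated for lists whose members vary together.

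Genes named in the text follow a rule set before the data were examined: the fixed genes, from each of 18 lists up to 3 members with the largest ratio and the one with most UMIs, the 10 genes at either end as defining genes, and each cluster's top 10 genes, the last 2 kinds among genes with at least 50 CPM and a UMI in at least 20% of the cells concerned. Some genes under this rule are left out of the text and of the figure of the fixed genes. Further members of a list named beside a small count, and genes given by cluster, were chosen after their values were seen. Alternatives covered the cell minimum, mitochondrial maximum, doublets, hashtag rule, clustering features and resolution, splitting of UMIs, free RNA, each hashtag left out, scaling and thinning, 23 planned and 6 added after seeing the data. Where filters, doublets, features, resolution or the hashtags used changed, cells were clustered and named again, so class limits moved too. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0 were used.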

Results

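The data are 1 RNA library and 1 matching hashtag library from a single pool of mouse cells. Bone marrow of 15-day-old mice was cultured for 8 days. The mice carried an iCre-hCD2 reporter for Gm38411 and a tdTomato reporter at R26. Cells were sorted as tdTomato and human CD2 positive and as negative for B220, CD3 and Ly6C, and the labels describe the product as ILC3s, the group 3 innate lymphoid cells, and dendritic cells. After doublet removal 24194 cells remained, with a median of 16193.5 UMIs and 4784 genes per cell. Hashtags 10, 11 and 12 marked 8185, 8624 and 7145 of these cells, with 140615992, 144755714 and 119312474 gene UMIs. The labels do not say what each hashtag marks. The hashtag populations are therefore given as values and not as replicates, and no test was made. Levels are counts scaled to equal class totals (CPM), and intervals are 95% intervals that cover counting error only.

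The first question was which cells the sorted culture held. Most cells belonged to 2 classes. DC-like cells made up 31.7% of all cells (7679 of 24194, exact binomial interval 31.2% to 32.3%) and ILC3-like cells 54.8% (13259, 54.2% to 55.4%). Cells resembling NK cells or ILC1s, led by Ncr1, Klrb1c and Xcl1, made up 9.97% (9.59% to 10.3%). Small groups resembled neutrophils (134 cells), monocytes or macrophages (37 cells) and B-lineage cells (30 cells). A further 644 cells, 2.66% of the total, lay in clusters without a name.

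Genes that separated the classes, and therefore define them, included Prdm16 and Flt3 on the DC-like side. Flt3 encodes the receptor for a growth factor of dendritic cells. Among genes with at least 50 CPM and a UMI in at least 20% of the cells of the higher class, the 10 with the highest DC-like over ILC3-like ratio were Adam23, Marchf1, Zfp366, Cdh1, Kynu, Adap2, St8sia6, Tbc1d9, Clec4a4 and Spint1. Those with the lowest ratio under the same limits were Il22, Tmem132d, Edil3, Zfp462, Ppp1r14c, Skap1, Il17f, Camk4, Cxcr6 and Igfbp7. Cdh1, Il22 and Il17f are members of the fixed lists, so they were neither clustering features nor naming markers. Of the markers used for naming, those of conventional type 2 dendritic cells were mostly present in DC-like cells: Clec10a stood at 489 CPM, Clec4a4 at 166, Sirpa at 148, Irf4 at 83.5 and Mgl2 at 78.1, with Cd209a low at 2.43. Of the type 1 markers Wdfy4 was abundant, at 802, while Xcr1 (1.28), Clec9a (0.737), Cadm1 (0.784) and Tlr3 (4.96) were low, and Irf8 stood at 70.5 against 49.5 in ILC3-like cells, within 2-fold. Batf3, listed as a DC marker, was lower in DC-like cells, at 19.5 against 42.5 CPM. The type 2 markers were uneven within the class, with Clec10a at 1059 CPM and Mgl2 at 218 in DC-like cluster 2.

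The 3 hashtag populations held the same classes in somewhat different shares. DC-like cells were 29.0% of hashtag 10 (28.1% to 30%), 32.9% of hashtag 11 (31.9% to 33.9%) and 33.1% of hashtag 12 (32.0% to 34.2%). The ILC3-like shares were 59.7%, 54.3% and 50.1% in the same order, and the NK cell or ILC1-like shares 8.04%, 9.90% and 12.3%. Of the DC-like clusters, cluster 10 ranged from 4.59% of hashtag 10 to 7.26% of hashtag 12. The sort sets which cells could enter these shares. The line between ILC3-like and NK cell or ILC1-like cells also moved with the clustering. With 1000 variable genes as features the ILC3-like share was 43.4% and the NK cell or ILC1-like share 19.9%, and with a stricter marker gap of 1.5 for a class name, chosen after seeing the data, the ILC3-like share was 23.3%.

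**Figure D1:**
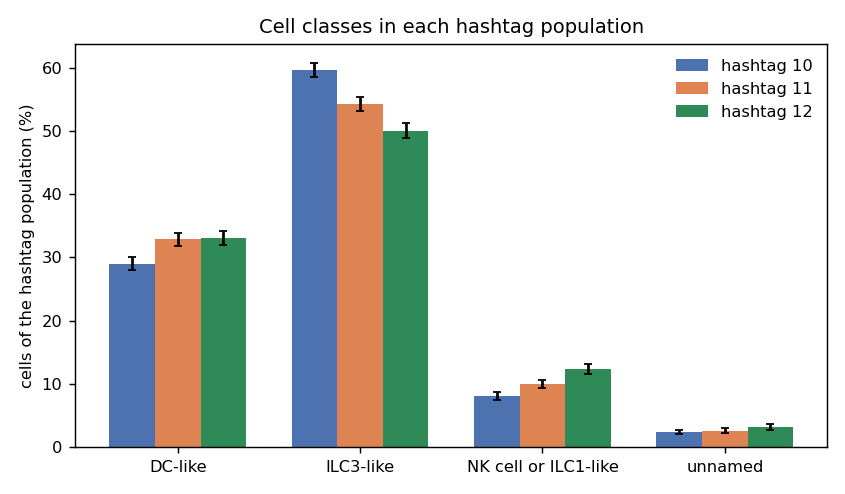
Percentage of the cells of each hashtag population (y axis) that fell in each class (x axis), for hashtags 10, 11 and 12. Bars are shares and error bars exact 95% binomial intervals; DC-like cells were 29.0% to 33.1% and ILC3-like cells 50.1% to 59.7% of a hashtag population.

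The second question was how the DC-like cells differed from the ILC3-like cells of the same culture. DC-like cells carried the antigen presentation machinery of MHC class II, most members of the myeloid and interferon response lists, and 7 of 11 genes compared from the list of Aire and epithelial or neural genes. ILC3-like cells carried lymphocyte cytokines and most of the transcripts of dividing cells. Gm38411, the long noncoding RNA gene whose reporter was used for the sort, was present in both. It stood at 80.6 CPM in DC-like cells (exact Poisson interval 79.0 to 82.2) and 105 in ILC3-like cells (103 to 106), below the 2-fold size rule (log2 ratio -0.38). After thinning to 10500 UMIs per cell, a Gm38411 UMI was seen in 47.8% of DC-like and 59.9% of ILC3-like cells, against 3.06% of the neutrophil-like cells. The share was 52.2% in NK cell or ILC1-like cells. Only 98 neutrophil-like cells could be thinned, and that group is mixed, as described below. Before thinning the DC-like and ILC3-like shares were 57.7% and 73.7%. Median depths were 16075 UMIs in DC-like, 16455 in ILC3-like and 25870 in neutrophil-like cells.

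Of the genes fixed for the comparison, Prdm16, a zinc finger transcription factor, was 67.6-fold higher in DC-like cells (258 against 3.81 CPM). Flt3 was 32.6-fold higher (140 against 4.29) and Zbtb46, a transcription factor of conventional dendritic cells, 5.33-fold higher (99.8 against 18.7). Ciita, the master regulator of MHC class II transcription, was 36.0-fold higher (234 against 6.51). Il7r, the receptor chain for interleukin 7, was 4.92-fold lower in DC-like cells (93.1 against 458), Gata3 was 3.14-fold lower (16.6 against 52.1) and Tbx21, which encodes T-bet, 2.56-fold lower (10.6 against 27.1). Zbtb46, Prdm16, Flt3, Il7r, Gata3 and Tbx21 were also markers for naming the clusters, so their ratios are not independent of the class names. Ccr7, a receptor that guides dendritic cells to lymph nodes, was 2.72-fold higher in DC-like cells (13.6 against 4.98). This rested partly on cluster 16, 139 cells with 750 of the 1712 Ccr7 UMIs of the class. The log2 ratio was 1.44, but 0.64 without that cluster (an alternative chosen after seeing the data), 0.72 with 4000 variable genes, 0.66 without hashtag 12 and 0.43 over cells with no G2/M UMI. That of Tbx21 was -1.36, but -0.79 with 1000 variable genes, -0.86 over cells with no G2/M UMI and -0.78 without the fully cycling clusters, and it was -1.97 without hashtag 10. The values without a hashtag came from cells clustered anew. With the main classes kept, Tbx21 stood at -1.41 to -1.34 and Ccr7 at 0.76 to 1.85 over the hashtag populations. Aire had 14 UMIs in DC-like cells and 0 in ILC3-like cells, and Itgb8 had 7 and 6, too few for a comparison. The features held no row for tdTomato, iCre or human CD2.

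**Figure D2:**
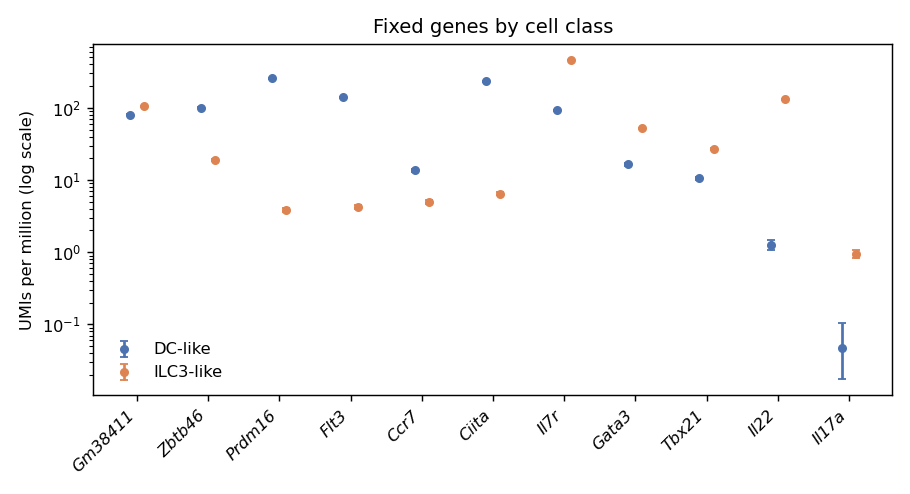
CPM on a log scale (y axis) for fixed genes with at least 50 UMIs (x axis), in DC-like and ILC3-like cells. Points are summed values and error bars exact 95% Poisson intervals; Gm38411 lies at 80.6 and 105 CPM, while Prdm16 lies at 258 and 3.81.

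All 13 members of the MHC class II presentation list had enough UMIs, and 12 were higher in DC-like cells, with a median log2 ratio of 4.86. H2-DMb2, a chain of the peptide-loading factor DM, was the most different (380 against 5.6 CPM, log2 6.08). H2-Eb1 stood at 3028 against 49.5 and H2-Aa at 3481 against 67.9. Cd74, the invariant chain, was the most abundant, at 5230 (5218 to 5243) against 190 (188 to 192). Ifi30 did not reach 2-fold. The list median lay above all of 10000 random lists of the same size and expression (percentile 100).

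MHC class I presentation went the other way where it differed. None of its 13 members was higher in DC-like cells, and 4 were lower: B2m, the light chain of class I molecules (972 against 2106 CPM, log2 -1.12), H2-K1 (493 against 1184, -1.26), H2-D1 (297 against 860, -1.53) and Nlrc5, the transcriptional activator of class I genes (10.7 against 39.9, -1.90). The other 9 members, among them the transporter genes Tap1 and Tap2 and the immunoproteasome genes, were within 2-fold, and the list median was 0.02 (percentile 72.7).

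Genes of the interferon response stood higher in DC-like cells, 11 of 13 by the size rule with a median log2 ratio of 2.44 (percentile 100). Mx1, an antiviral GTPase, was at 34.4 against 0.868 CPM (5.31), Ifit3 at 16.5 against 0.895 (4.20) and Oas1a at 18.3 against 1.88 (3.29). Irf7 did not reach 2-fold (0.99).

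Of 16 myeloid genes compared, 11 were higher and 2 lower in DC-like cells, with a median log2 ratio of 3.13 (percentile 100). Cybb, a subunit of the phagocyte oxidase, was at 89.0 against 0.983 CPM (6.5), Itgam, the integrin chain CD11b, at 921 against 11.7 (6.29) and Clec7a at 7.91 against 0.115 (6.11). Cebpb and Zeb2 were the 2 lower members. Fcer1g, the most abundant, was at 394 against 556 (-0.50).

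In the list of Aire and epithelial or neural genes, 7 of 11 genes compared were higher in DC-like cells and 1, the cadherin Cdh2, was lower (median log2 4.74, percentile 100). Pigr, the polymeric immunoglobulin receptor, was at 7.65 against 0.0529 CPM (7.18). Cdh1, which encodes E-cadherin, was at 135 against 0.987 (7.10), and the adhesion gene Epcam at 37.3 against 0.560 (6.06). Col17a1, Nrn1 and Gal were also higher.

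Lymphocyte effector cytokines were lower in DC-like cells in 10 of 11 cases, with a median log2 ratio of -3.42 (percentile 0). Il22, a cytokine that acts on epithelia, was at 1.28 against 131 CPM (-6.68, a 102-fold difference), and Il17f at 0.792 against 52.4 (-6.05). Free RNA, not taken off here, held Il22 at 77.3 CPM, and the log2 ratio of Il22 ranged from -8.00 to -6.22 over the alternatives. Lta was at 7.33 against 155 (-4.40) and Il17a at 0.0475 against 0.952 (-4.32). Ltb, the most abundant member, was at 451 against 640 and within 2-fold (-0.50).

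Surface signals split. Of 10 costimulation and checkpoint ligands, Cd86 (71.3 against 2.54 CPM, log2 4.81), Cd80 (50.9 against 3.39, 3.91), Cd40 and Cd274 (59.8 against 15.8, 1.92) were higher in DC-like cells. Tnfsf4 (0.523 against 5.06, -3.27) and Cd70 were lower, and the list median was -0.08 (percentile 59.6). That median ranged from -0.30 to 0.70 over the alternatives. Of 13 growth factor and cytokine receptors, 5 were higher and 5 lower (median -0.29, percentile 20.5). Il6ra (45.1 against 0.397, 6.83) and Csf2rb (117 against 2.15, 5.77) were higher. Il12rb1 (2.08 against 74.2, -5.16) and Ifngr1 (289 against 1240, -2.10) were lower.

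Chemokine receptors and homing genes were higher in 7 and lower in 5 of 15 cases (median 0.12, percentile 84.5). Over the alternatives this median ranged from -0.01 to 1.30. Itga4, the integrin chain of VLA-4, was at 1611 against 340 CPM (2.25) and was among the higher members. Cxcr3 (0.412 against 6.63, -4.01) and S1pr1 (0.563 against 8.48, -3.91) were lower. Among 11 chemokines, Cxcl16 (35.9 against 0.564, 5.99) and Ccl5 (156 against 12.6, 3.63) were higher, and 5 were lower, among them Ccl3 (1.06 against 19.4, -4.20) and Cxcl10 (5.56 against 74.9, -3.75). The chemokine median of -0.79 (percentile 1.71) ranged from -2.95 to 0.08 over the alternatives. The log2 ratio of Ccl3 was -0.38 with 1000 variable genes, -2.53 without hashtag 10 and -1.74 without hashtag 12, with cells clustered anew. Ccl3 stood at 610 CPM in ILC3-like cluster 15 (319 cells), where 10 of 11 chemokines were higher than in the rest of that class. The Ccl3 ratio thus rested partly on that cluster, and no alternative left it out. Of the 19675 Ccl5 UMIs in DC-like cells 15835 lay in cluster 9. The log2 ratio of Ccl5 was 1.54 without that cluster, an alternative chosen after seeing the data, and 1.52 without hashtag 10 after clustering anew. Of 9 members of the list of TGF-beta activation and tolerance genes that could be compared, Aldh1a2, an enzyme that makes retinoic acid (8.49 against 0.256, 5.05), and Tgfb2 were higher, while Itgav, Tgfb3 (0.951 against 3.79, -2.00) and Aldh1a3 (0.182 against 0.811, -2.15) were lower. Over cells with no G2/M UMI the log2 ratio of Aldh1a2 was 3.06. The list median was 0.18 (percentile 81.7), and its most abundant member Tgfb1 stood at 131 against 116.

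Early lymphoid genes also went both ways, with 4 higher and 5 lower of 13 compared (median -0.62, percentile 1.74). Ets1 (10.9 against 298 CPM, -4.78), Notch1 (3.61 against 37.2, -3.37) and Bcl11b (3 UMIs, 0.0238 against 0.599; log2 -4.66, interval -6.95 to -3.08) were lower in DC-like cells. The higher members were Ighm, Bcl11a, Cd2 and Cd27. Ikzf1 stood at 468 against 401 (0.22). Rag1, Rag2, Dntt and Ptcra had fewer than 50 UMIs over both classes.

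In the NF-kB and TNF receptor family list (13 genes, median 0.28, percentile 98.5), Rel was higher (208 against 80.9, 1.37) and 3 members were lower, among them Tnfrsf9 (5.42 against 104, -4.26) and Traf1 (17.7 against 86.9, -2.29). Nfkbia was at 390 against 665 (-0.77, and between -1.05 and -1.23 in 5 alternatives). Of 11 immediate early and stress genes, Fosb (20.7 against 1.76, 3.55), Zfp36 (109 against 19.9, 2.45), Egr1 (114 against 27.1, 2.07), Atf3 and Junb were higher (median 0.83, percentile 99.7), and Ier2 was at 203 against 197. None of 12 glycolysis genes reached 2-fold (median -0.58, percentile 0.70), with Pkm at 180 against 344 (-0.93) and Gapdh at 683 against 867. Some passed it in alternatives: over cells with no G2/M UMI Pkm (-1.17) and Eno1 (-1.12) were lower and Slc2a1 (1.11) higher, with the marker gap of 1.5 they stood at -1.14, -1.09 and 1.01, and without hashtag 10 Pkm was at -1.02 and Slc2a1 at 1.03. Of 12 cholesterol synthesis genes, Insig1 was higher (41.5 against 19.4, 1.10; 0.97 with the marker gap of 1.5) and the rest within 2-fold (median 0.24, percentile 98.4), although Lss had a log2 ratio between -1.01 and -1.09 in 4 alternatives.

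Over the 18 lists, 224 of 243 members could be compared, of which 72 were higher and 67 lower in DC-like cells by the fixed size rule. Over all 15876 genes compared, 2093 were higher and 2789 lower by the same rule. Classes held 126204072 and 226896917 gene UMIs. There is 1 library, so the ratios have no replicate check and no p-value. For each hashtag left out cells were clustered and named again, so new class limits also enter the ratios. In this way 22 called genes had a ratio that moved by over 1.5-fold, all keeping their direction. Besides those given above, without hashtag 10 these included S1pr1 (-5.82), Lta (-5.80), Ets1 (-5.67), Rrm2 (-4.77), Cxcl10 (-4.63), Top2a (-4.13), Bcl11b (-3.07), Tgfb3 (-2.91), Aldh1a3 (-2.89), Il17a (-2.88), Cdc6 (-2.74), Aldh1a2 (6.15), Cxcl16 (6.62), Clec7a (7.37) and Pigr (8.44). Without hashtag 12 Csf2rb (6.37), Ifit3 (3.23) and again Aldh1a2 (6.16) and Bcl11b (-5.45) moved, and without hashtag 11 Bcl11b (-3.41). The list genes were kept out of the clustering features, but genes that vary with them were not.

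**Figure D3:**
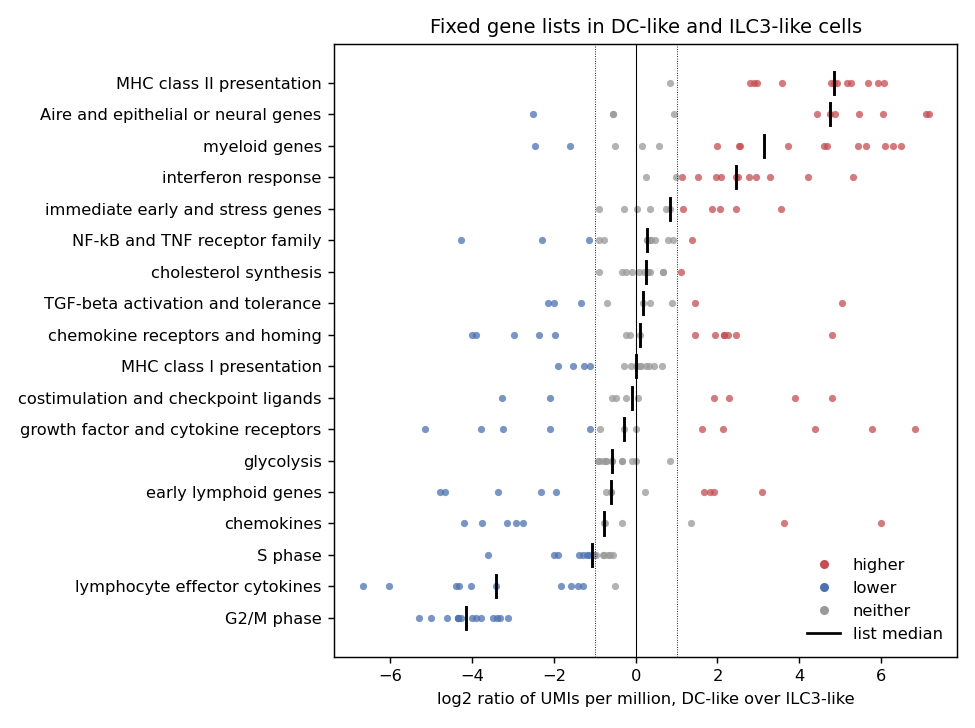
Log2 ratio of CPM, DC-like over ILC3-like (x axis), for each member of the 18 fixed lists (y axis) with at least 50 UMIs; colours mark members higher, lower or neither by the size rule, black bars the list medians and dotted lines 2-fold. The medians run from -4.14 for G2/M phase to 4.86 for MHC class II presentation.

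The next question was what share of each class carried transcripts of dividing cells. After thinning every cell to 10500 UMIs, 65.0% of ILC3-like cells (7884 of 12128, 64.2% to 65.9%) and 13.9% of DC-like cells (972 of 7004, 13.1% to 14.7%) had a UMI of at least 3 genes of the G2/M list. The share was 25.9% in NK cell or ILC1-like cells (530 of 2049). All thinned cells of ILC3-like clusters 3 (2439) and 5 (2193) had such UMIs and count towards the 65.0%. Whether these clusters also hold NK cell or ILC1-like cells was not tested. Without the fully cycling clusters the log2 ratio of Tbx21 was -0.78 in place of -1.36. The gap between the ILC3-like and NK cell or ILC1-like shares may thus follow in part from clustering and naming. Over the hashtag populations the share ranged from 64.2% to 66.2% in ILC3-like and from 13.0% to 15.1% in DC-like cells. Thinning left out 1131 ILC3-like and 675 DC-like cells, and without it the shares were 67.7% and 22.1%. Cells that pass this cutoff are called cycling, but no alternative varied the cutoff of 3 genes. In ILC3-like cluster 1, 42.2% of cells passed although all 14 G2/M genes were lower there than in the rest of the class (median -3.95). The shares are therefore not counts of dividing cells. All 14 G2/M genes were lower in DC-like cells (median log2 -4.14, percentile 0), with Hmmr at 2.98 against 118 CPM (-5.31), Cenpf at 6.95 against 222 (-5.00), Plk1 at 2.39 against 58.3 (-4.61) and Top2a at 90.4 against 955 (-3.40). Of 14 S phase genes, 8 were lower (median -1.07, percentile 0.01), among them the ribonucleotide reductase subunit Rrm2 (19.9 against 243, -3.61), Tyms (36.0 against 143, -1.99), Cdc6 (20.6 against 76.6, -1.89) and Pcna (140 against 343, -1.29), whose ratio was within 2-fold without the fully cycling clusters (-0.86) and with the marker gap of 1.5 (-0.84). Over cells with no G2/M UMI the S phase median was -0.38, and Tyms (-0.42) and Pcna (-0.30) were within 2-fold.

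A further cycling cluster had no class. Cluster 13 (545 cells, 2.25% of all cells) held cells with a DC marker score 2.05 log2 units above the ILC3 score, and all 528 of its thinned cells were cycling. It stayed unnamed because Cox6a2, listed as a marker of plasmacytoid dendritic cells, led its genes and no DC marker was among its top 10. With it the DC-like share of cycling cells was 19.9% (1500 of 7532, 19.0% to 20.8%). It made up 2.05%, 2.21% and 2.59% of hashtags 10, 11 and 12. With the marker gap of 1.5 the ILC3-like share of cycling cells was 45.4%.

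**Figure D4:**
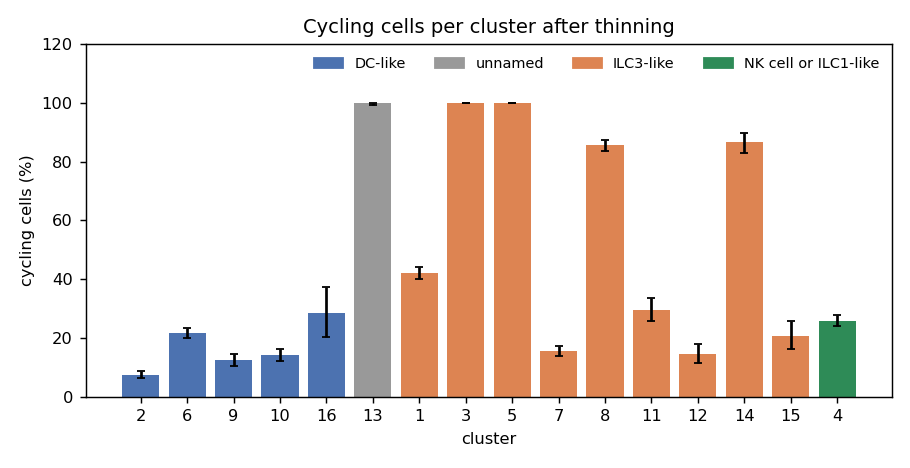
Percentage of thinned cells with a UMI of at least 3 G2/M genes (y axis) in each cluster with at least 100 thinned cells (x axis), coloured by class; error bars are exact 95% binomial intervals. Clusters 3, 5 and 13 are at 100%, and DC-like clusters lie between 7.5% and 28.3%.

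Within the DC-like class, 5 clusters differed in MHC class II, chemokine receptor, costimulation and epithelial or neural genes. Cluster 2 (2518 cells), led by Mgl2, Prdm16, Clec10a and Epcam, held the highest Cd74 (6933 CPM) and Prdm16 (607), and of 10 genes of the epithelial or neural list 5 were higher and 3 lower there than in the rest of the class (median log2 1.14). Of 15 chemokine receptor and homing genes 10 were lower there (median -1.68). Cluster 6 (2181 cells), led by Bex6, Cdh17 and Ccnd1, had no member of the MHC class II list that differed by 2-fold from the rest (median -0.52). Cluster 10 (1415 cells), led by Rnd3, Btla and Clec4a2, also had high Cd74 (6141), and its Cybb (182) was close to that of cluster 16 (179). Of the epithelial or neural list 8 of 10 genes were lower there than in the rest of the class (median -2.12). Cluster 16 (139 cells), led by Dpp10, Ccl22 and Anxa3, had 11 of 13 NF-kB genes (median 1.74), 7 of 9 costimulation genes (1.76) and 12 of 14 G2/M genes (1.40) higher than the rest of the class, and 8 of 13 interferon response genes lower (-1.32). Its share of cycling cells, 28.3% (34 of 120, 20.5% to 37.3%), was the highest of the DC-like clusters. The interval overlapped that of cluster 6 (21.6%, 19.8% to 23.5%). In cluster 16 Ccr7 stood at 368 CPM against 0.941 to 16.2 in the other 4 clusters, and Relb at 558 against 94.8 to 139.

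Gm38411 differed among these clusters. It was at 17.5 CPM in cluster 10 and at 34.4 to 127 in the other DC-like clusters, with 127 in cluster 2, 72 in cluster 6 and 79.8 in cluster 9. Zbtb46 (118) and Flt3 (135) in cluster 10 were close to their levels in cluster 2 (110 and 147).

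Cluster 9 (1426 cells), led by Ccl5, Cacnb2 and Fscn1, combined DC genes with genes of innate lymphoid cells. Its DC marker score stood 1.02 log2 units above its ILC3 score, against 2.04 to 3.19 in the other DC-like clusters. Its class name is thus the least firm among them, and it has none at the marker gap of 1.5. Its Tox level was 1281 CPM against 35 to 231 in the other DC-like clusters, and Rora was at 406 against 45.2 to 275. Tcf7 was at 270, close to the 323 of cluster 16 and above the 10.1 to 33.2 of the other 3 clusters. Of 10 early lymphoid genes 5 were higher than in the rest of the class (median 0.99) and of 13 MHC class II genes 9 were lower (median -1.47). Of 15 chemokine receptor and homing genes 9 were higher and 2 lower (1.28), and of 11 immediate early and stress genes 7 were lower (-1.16). Flt3 was at 94.8 and Itga4 at 3155, the highest of the DC-like clusters.

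**Figure D5:**
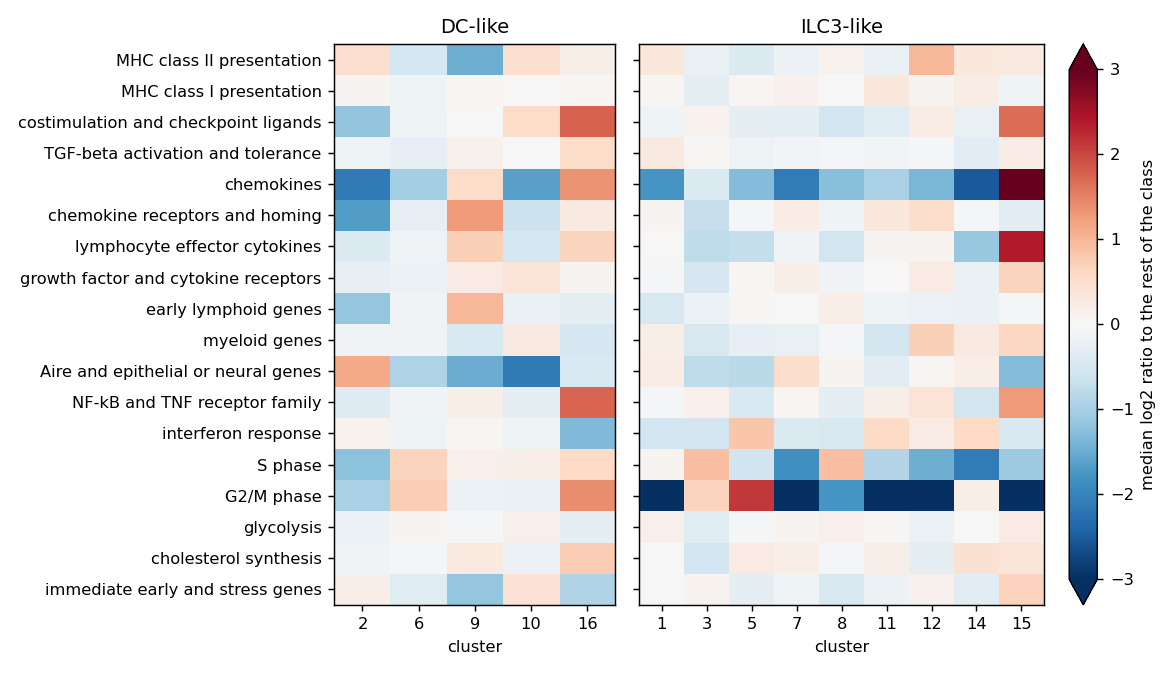
Median log2 ratio of each fixed list (rows) in each cluster (columns) to the other cells of its class, DC-like on the left and ILC3-like on the right; the colour scale stops at -3 and 3. Cluster 16 stands out for NF-kB genes (1.74), cluster 9 for lower MHC class II (-1.47) and cluster 15 for chemokines (4.54).

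Within the ILC3-like class, clusters 3, 5, 8 and 14 consisted mostly of cycling cells (85.6% to 100%), and the others differed in cytokines. Cluster 15 (319 cells), led by Ccl3, Crtam, Xcl1 and Csf2, had 10 of 11 chemokines (median log2 4.54) and 7 of 11 effector cytokines (2.38) higher than the rest of the class. So were 9 of 10 costimulation genes (1.68), 8 of 13 NF-kB genes (1.27) and 4 of 11 immediate early and stress genes (0.68). All 14 G2/M genes were lower there (-3.88), as they were in clusters 1, 7, 11 and 12 (-4.91 to -3.95), so this is not particular to cluster 15. Egr3 and Nr4a3 were among its top 10 genes. In cluster 15 Il22 stood at 623 CPM and Csf2, a growth factor for myeloid cells, at 765. Cluster 11 (872 cells), led by Il17f, had the next highest Il22 (343) and the highest Gm38411 of the class (179). Cluster 12 (627 cells), led by Cp, Hp and C3, had 7 of 13 MHC class II genes higher than the rest (median 1.0), with Cd74 at 534 CPM against 90.1 to 469 in the other ILC3-like clusters, and no cluster of this class approached the 2382 of the lowest DC-like cluster. In cluster 12, 5 of 13 myeloid genes were higher too and 1 was lower (median 0.71). Hp was also among the top 10 genes of the monocyte or macrophage-like cluster. Il22 was at 9.52 in cluster 14 and between 57.9 and 187 in clusters 1, 3, 5, 7, 8 and 12. Gm38411 was at 42.3 to 179 over all 9 clusters. Clusters are built from the same UMIs, so their leading genes define them and are not results. The values have no replicate check.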

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

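Of the tests in this part, those of the ratio of class II to other DC-restricted genes and of dividing cells were set before their values were seen, and the other 5 were chosen after the pattern was seen.

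Cells of 3 other kinds were found outside the comparison of DC-like and ILC3-like cells, although the sort excluded B220, CD3 and Ly6C. Each count was above the limit of 3 that a count of 0 allows. A named cluster needs at least 20 cells, so this was fixed in advance and is no evidence for these kinds. Neutrophil-like cells numbered 134, with S100a9 at 9815 CPM; a UMI of S100a9 was in 17.3% of the 98 that could be thinned and of Flt3 in 50%, so the group is mixed. Monocyte or macrophage-like cells numbered 37, with Lyz2 at 17921. B cell-like cells numbered 30, of which 24 carried hashtag 12, with Ebf1 at 5526. The median doublet scores of these groups, 0.164, 0.144 and 0.166 in the same order, were the highest of the 21 clusters (0.0359 to 0.0995 in the others), and the neutrophil-like cells had the greatest median depth, 25870 UMIs.

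DC-like cluster 9, picked as the DC-like cluster highest in Tox, carried genes of innate lymphoid cells. With the level of the other DC-like clusters taken off both, it stood at a median of 53.5% of the ILC3-like level over the 5 of 7 progenitor markers that separated the classes (13.7% for Pdcd1 to 115% for Tcf7), or 41.7% without Tox. Capture of an ILC3-like cell in the same droplet would bring all abundant ILC3 transcripts. Over 98 genes restricted to ILC3-like cells the median share, taken in the same way, was 5.58% (3.13% to 7.66% over resampled genes), with Cxcr6 at 3.02%, and the cluster's median of 14274.5 UMIs was below the 16437 of the other DC-like cells. Free RNA also falls short, since the markers stood at a median of 88.9 times what it brings, or 86.6 without Tox. No biological explanation was tested.

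MHC class II transcripts were seen in ILC3-like cells, with a UMI of H2-Aa in 39.0% of them after thinning. The free RNA in droplets without a cell is too small a source, if droplets with a cell hold the same amount. On that basis 9 class II genes stood at a median of 7.78 times what it brings (4.14 to 22.3). Class II genes stood at 2.78% of their DC-like level and 85 other DC-restricted genes at 4.18%, a ratio of 0.664 (0.371 to 1.15), which droplets shared with a DC-like cell would give but which does not single them out. Such droplets would carry many UMIs of the other DC-restricted genes. The 1212 thinned ILC3-like cells with most UMIs of those genes were left out, more than the doublets within a hashtag still expected (1683 less the 768 called). Class II levels in the rest kept a median of 77.4% (73.4% to 83.1% over resampled cells), and a UMI of H2-Aa was in 37.7% of them. Shared droplets therefore fall short as the whole source, and a smaller part from them stays open. Those kept held a mean of 12.2 UMIs of the other DC-restricted genes, against 32.0 in those left out and 265 in thinned DC-like cells. A low level of DC transcripts spread over most ILC3-like cells was therefore not excluded. Cluster 12 was not tested apart, and no biological explanation was tested.

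B2m, H2-K1, H2-D1 and Nlrc5 were lower in DC-like cells, with a median log2 ratio of -1.40. With median-ratio scaling it was -1.30. That scaling raises every log2 ratio by the same 0.10, so the result follows from the size of the shift alone. A shift of this size is too small to account for the lower levels. Over the 2493 DC-like and 868 ILC3-like cells with no G2/M UMI after thinning the median log2 ratio was -1.41. The larger share of cycling ILC3-like cells therefore does not account for the lower levels either. No biological explanation was tested.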

How the results depend on the processing

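Of 29 alternatives, 23 were fixed before the data were examined and 6 were chosen after seeing them: clusters led by another type kept in their class, marker gaps of 0.25 and 1.5, and fully cycling clusters, cluster 16 or cluster 9 left out. No paired analysis was possible because the libraries hold different measurements, RNA and hashtags, of the same cells, and no group has a second sample. Over the alternatives the 66 genes that the naming rule takes and that were higher or lower gave 1782 values, 1781 in the same direction and 1766 at least 2-fold. Over cells with no G2/M UMI, Il17a, Aldh1a3, Bcl11b, Hmmr and Plk1 had too few UMIs to compare, but their values are among the 1782. Of 189 medians of the 7 lists beyond 1 log2 unit, 188 kept their direction. List members higher in DC-like cells numbered 68 to 75 and lower members 47 to 74. Over only cells with no G2/M UMI the G2/M median was 0.11 and Hmmr 1.03, which follows from how those cells were chosen.

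Shares depended on clustering and filters, and beyond the settings' construction the cause was not tested. Values follow as DC-like share, ILC3-like share, cycling DC-like and cycling ILC3-like cells, in percent, with those inside the binomial interval left out. With 500 UMIs and 300 genes as minimum (29887 cells) they were 29.9, 47.5 and, for cycling ILC3-like cells, 67.8. With 2 times the UMI minimum (26620 cells) they were 30.04, 51.4 and, for cycling ILC3-like cells, 66.6. They were 30.9, 52.7, 12.3 and 66.0 with a mitochondrial maximum of 5%, 28.7, 48.3, 13.0 and 63.4 with doublets kept, and 30.4, 50.2, 12.7 and 63.8 with hashtags alone for doublets. They were 30.8, 58.4, 12.1 and 61.2 without barcodes lacking a hashtag, 30.9, 46.2, 12.2 and 66.0 with the fixed lists among the features, and 24.4, 52.0, 12.3 and 66.0 with UMIs split between clustering and values. A mitochondrial maximum of 20% gave shares of 25.4 and 48.2 and 66.8 cycling ILC3-like cells, and resolution 2 gave 28.3, 47.9 and 62.0. The ILC3-like share was 43.4 with 1000 and 52.8 with 4000 variable genes and 48.8 at resolution 0.5, where 63.4 of ILC3-like cells were cycling. Without thinning 22.1 and 67.7 were cycling. Keeping clusters led by another type gave a DC-like share of 34.0, with 19.9 cycling. A marker gap of 1.5 gave shares of 25.8 and 23.3 and 45.4 cycling ILC3-like cells. Leaving out each hashtag and clustering anew gave ranges of 23.0 to 30.7, 47.7 to 55.2, 10.0 to 13.9 and 63.1 to 68.9. With the top hashtag at 80% of hashtag UMIs the DC-like shares of hashtags 10, 11 and 12 were 29.0, 32.9 and 33.2.

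Depth limits rare transcripts. Aire, with 14 UMIs, and Itgb8, with 7 and 6, were below the minimum of 50.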

Other observations

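The NK cell or ILC1-like cells, which entered no comparison of the report, had the naming markers Ncr1 (213 CPM), Klrb1c (425) and Nkg7 (330) among their top 10 genes. Il22 was lower than in ILC3-like cells (36.0 against 131, log2 -1.86), as was Il17f (3.90 against 52.4, -3.75). Ifng, the type 1 effector cytokine, was higher (3.14 against 0.595, 2.40), as were Ccl5 (160 against 12.6, 3.66), Xcl1 (405 against 88.3, 2.20), Cxcr3 (38.3 against 6.63, 2.53) and Ccr9 (27.2 against 4.33, 2.65).

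By the same size rule 8 of 13 interferon response genes were higher in the NK cell or ILC1-like cells than in ILC3-like cells (median log2 1.02), among them Ifit3 (2.97), Ifit1 (2.77) and Mx1 (2.60). Of 13 early lymphoid genes 6 were higher (median 0.94), among them Cd2 (3.84) and Bcl11b (4.30 against 0.599, 2.84). All 14 G2/M genes were lower (median -4.01). ILC3-like clusters 1, 7, 11, 12 and 15 also had all 14 lower than the rest of their class (medians -4.91 to -3.88). The ILC3-like class includes clusters 3 and 5, in which every thinned cell was cycling and which cell cycle genes led. The low G2/M level may thus follow from clustering and naming, and does not set these cells apart. The genes named here were chosen after their values were seen.

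Of the 14 Aire UMIs in DC-like cells, 11 lay in cluster 16, at 5.40 CPM (2.70 to 9.67), and 3 in cluster 9.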
